A study of Caenorhabditis elegans with 2 samples.

How the data were processed

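Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans hermaphrodites of strain YL581, collected as young adults 50 hours after synchronization at the starved L1 stage. Per the labels, the worms carried REC-8, the meiosis-specific kleisin subunit of cohesin, fused to GFP, chromatin was sheared by sonication, and an anti-GFP antibody was used. The antibody field of the labels names rec-8 itself, so the labels differ on this point. The 2 samples are biological replicates of 1 group. The labels point to a different protocol document for each of them. A control is named in the labels and is not analysed here, and no sample without the tag is analysed here.

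The deposited files are lists of peaks, called by the authors for each replicate alone and for both replicates pooled, with a control, per the labels and the file listings deposited with the samples. A further list, called the thresholded list here, holds the pooled peaks that passed the authors' threshold on the irreproducible discovery rate. That rate measures how well peak ranks repeat between lists. A place on the thresholded list does not by itself show a peak in each replicate. Each list exists for builds ce10 and ce11. In the deposited lists each peak has the peak caller's signal value, which was not scaled between lists and is used here only to rank and describe peaks within a list. The deposited −log10 q value of each peak reached the list's highest value in 85.1% of the thresholded peaks and was not used for ranking. Aligner, peak caller and their versions are not given in the sources used here. Read counts are not analysed here, so the sequencing depth behind each peak is unknown. Without depth, a peak missing from 1 list cannot be read as an absence of signal.

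Coordinates are those of ce11, which is WBcel235, counted from 1. All 6 nuclear chromosomes held their last peak within the length of the reference sequence. Gene models were those of Ensembl release 115, and tRNA isotypes came from the RefSeq annotation of the same assembly. The ce10 lists were used for counts, replicate overlap and rank correlation, and the shares of peaks per chromosome. Chromosome lengths of ce11 served as the yardstick for the share on X. The mitochondrial genome was left out of all comparisons except replicate overlap and rank correlation.

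Peaks were represented by their summits. Random placements moved each summit to a random position of its own chromosome 1000 times, which gives a smallest 2-sided permutation p of 0.0020. Replicates were compared over the 739 strongest peaks of each, the length of the thresholded list, and a peak was shared when at least 50% of the shorter peak was overlapped. The rank correlation used 100000 permutations, which give a smallest p of 1e-05. Chromosome shares were tested with 2-sided exact binomial tests. Promoter windows ran from 1000 bp upstream to 500 bp downstream of protein-coding transcript starts. Gene lists and gene classes were tested with 2-sided Fisher's exact tests against all protein-coding genes, with Benjamini-Hochberg adjustment over the 15 lists or the 175 classes with at least 10 members. Of the symbols written out in the lists, 8 did not match a protein-coding gene. Non-coding genes counted as marked when a summit lay within 250 bp, and pseudogenes were not tested. In the division of the genome into parts, protein-coding genes took precedence, so that a tRNA gene inside an intron counted as intron. GC content and 6-mers were taken from 200 bp centred on the summit. For GC content, the difference from the mean of the flanks centred 1000 bp to both sides was tested with 10000 random sign flips. The 6-mers were compared with 200 bp centred 1000 bp to a randomly drawn side, with exact McNemar tests adjusted over 2080 6-mers. Intervals are exact 95% binomial intervals, cover counting error only and treat peaks as independent, although neighbouring peaks are not.

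The rules for named items were fixed before the data were examined. They took the 20 strongest thresholded peaks, up to 4 members of each list with the highest signal, rec-8, unc-119, coh-3 and coh-4 in every case, the 5 gene classes and 6-mers with the lowest adjusted p on each side, and every non-coding biotype with at least 10 genes. The alternatives were other overlap rules, windows, yardsticks, backgrounds, the ce10 lists, the stronger part of the thresholded list and each replicate's own list. Merging overlapping peaks and leaving out summits near tRNA, snoRNA, snRNA or rRNA genes were added after the data were seen, as was keeping only tRNA genes with no other tRNA gene that the same summit could mark.

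The statistics were tested on simulated data with 733 summits. With summits planted in 200 tRNA genes and at the starts of 20 ribosomal protein genes, 2 biotypes passed against 200 random placements. These were tRNA (adjusted permutation p = 0.045) and ncRNA, both at the smallest p that 200 placements can give. With only 1 biotype at that p the adjusted value would not have passed, so this run tests the biotypes weakly. Of the gene lists 1 passed, the ribosomal proteins (adjusted Fisher's exact p = 2.5e-22). A planted 6-mer had rank 5 of 2080 by p, in the same set as the planted tRNA genes. In 20 sets of random summits, 1 list, 1 class and 1 6-mer were called in all. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.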

Results

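REC-8-GFP ChIP-seq of young adult worms gave 739 thresholded peaks in ce11, of which 733 lay on the 6 nuclear chromosomes and 6 on the mitochondrial genome. The relaxed lists held 17532 peaks for replicate 1, 14069 for replicate 2 and 10019 for the pooled replicates. The median width of the thresholded peaks was 430 bp. The thresholded peaks were the 739 strongest of the pooled list. In ce10 the thresholded list held 765 peaks. Depth is unknown, since the files are peak lists.

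The replicates recovered largely the same strong peaks. Of the 739 strongest peaks of replicate 1, 480 (65.0%, 95% interval 61.4 to 68.4) overlapped one of the 739 strongest of replicate 2. Random placement gave 0.333% (permutation p = 0.0020, 2-sided, the smallest the placements can give). Over the 480 shared pairs the signals of both replicates correlated across peaks, which are not independent replicates (Spearman rho = 0.65, permutation p = 1e-05, the smallest the permutations can give). Among these pairs, 222 had a tRNA gene within 250 bp of the replicate 1 summit. Over all peaks of both relaxed lists 5260 of 17532 peaks of replicate 1 overlapped one of replicate 2, against 6.16% at random. Of the 733 nuclear thresholded peaks, 476 (64.9%) overlapped one of the 739 strongest peaks in each replicate. With all peaks of each relaxed list counted, 731 (99.7%) overlapped a peak in both replicates. The thresholded list is itself drawn from both replicates pooled, so these shares are not an independent check of them.

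**Figure D1:**
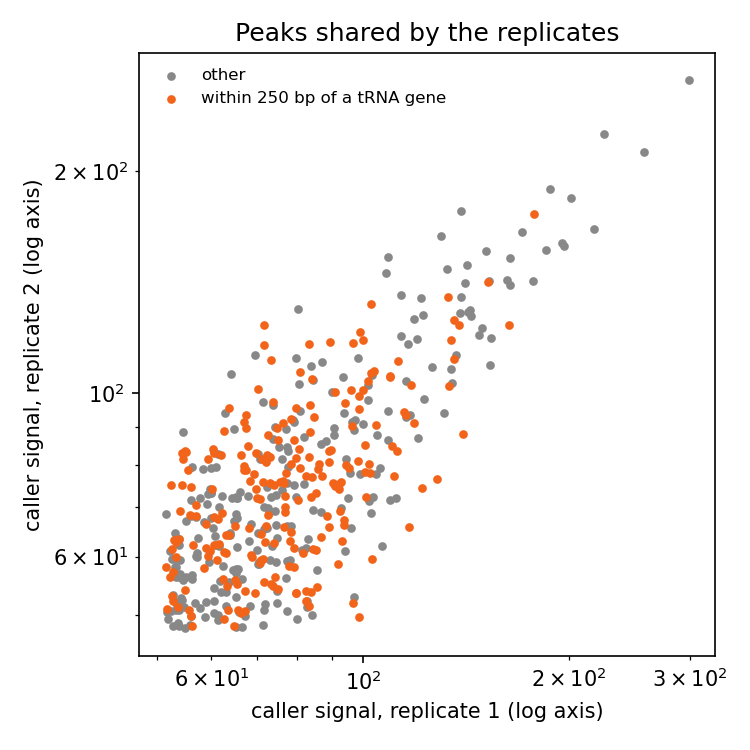
Caller signal of the 480 peaks shared by the 739 strongest peaks of each replicate, replicate 1 on the horizontal and replicate 2 on the vertical axis, both logarithmic. Each point is a pair of overlapping peaks, orange where a tRNA gene lies within 250 bp, and the points rise together (Spearman rho = 0.65).

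Most of the strongest nuclear peaks lay at small non-coding RNA genes. Among the 20 strongest thresholded peaks, 15 were nuclear and 5 mitochondrial. Of the 15 nuclear peaks, 9 lay within 250 bp of a snoRNA gene, 1 of a tRNA gene and 1 of a snRNA gene. The strongest nuclear peak (V, 8500413 to 8500713, signal 578) lay in an intron of pxn-1, 11 bp from the start of the snoRNA gene ZK994.7. A peak on V (12303507 to 12303751, signal 450) had its summit in an intron of frm-7 and inside the snoRNA gene C51F7.4. The intergenic peak on II from 11960723 to 11960946 (signal 383) was 77 bp from the start of the snoRNA gene W03C9.9. The intergenic peaks on I from 5706862 to 5707120 (signal 354) and from 8224333 to 8224539 (signal 353) were 63 bp and 40 bp from the starts of T19B4.8 and T02E1.9. Further snoRNA starts next to these strongest peaks were B0334.12 in an intron of twk-5 (II, 11484719 to 11484859, signal 344) and T03F7.8 in an intron of cutl-18 (V, 11314133 to 11314317, signal 317). The others were ZK265.10 (I, 8259543 to 8259676, signal 311) and T06C12.16 (V, 15873732 to 15874161, signal 310), both intergenic.

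The remaining nuclear peaks of the 20 strongest lay at other short RNA genes or upstream of protein-coding genes. The peak on I from 13463831 to 13464070 (signal 382) had its summit in rpr-1, the RNA of RNase P, within an intron of ints-8. The peak on X from 9743608 to 9743816 (signal 360) had its summit in an intron of him-4. That summit was 28 bp from the start of the ncRNA gene F15G9.8 and between the tRNA genes F15G9.t1 and F15G9.t2. The peak on II from 12944662 to 12944774 (signal 310) lay in an intron of F58G1.7, 200 bp from the start of the snRNA gene sup-6. Intergenic peaks on III lay 285 bp from the start of rpl-3 (3867468 to 3867697, signal 372), 461 bp from that of rpl-35 (7854624 to 7854788, signal 342) and 510 bp from that of K12H4.5 (8043845 to 8044079, signal 469).

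The mitochondrial peaks among the 20 strongest included the strongest peak of the list (4477 to 5015, signal 5247), with its summit inside the protein-coding gene MTCE.21. The others had their summits in ND1 (1921 to 2350, signal 807, and 1675 to 2104, signal 400) and in the rRNA gene MTCE.7 (1377 to 1806, signal 731, and 1031 to 1460, signal 687). None of the 17532 peaks of replicate 1 was mitochondrial, while 18 of the 14069 peaks of replicate 2 were. The 6 mitochondrial peaks of the thresholded list therefore have no partner in replicate 1.

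tRNA genes were the non-coding class with the highest share of marked genes. Of 612 nuclear tRNA genes, 326 (53.3%, interval 49.2 to 57.3) had a thresholded summit within 250 bp, against a mean of 2.78 in random placements. These genes accounted for 296 of the 733 summits (40.4%). Of 346 snoRNA genes, which guide the modification of other RNAs, 72 (20.8%) had a summit, against 1.55 at random. Of 129 snRNA genes, many of whose products serve in splicing, 22 (17.1%) had one, against 0.540 at random. The adjusted permutation p was 0.0036 for each of these classes. Summits at snoRNA genes had a median signal of 194, those at tRNA genes 137, and those at protein-coding starts away from such genes 114.

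The shares of the other non-coding biotypes were lower in these lists, a difference between biotypes that was not tested. Of 7764 ncRNA genes, 297 (3.83%) had a summit, against 38.7 at random (adjusted permutation p = 0.0036). Of these 297, 222 overlap a tRNA, snoRNA, snRNA or rRNA gene on the opposite strand. Without summits near tRNA, snoRNA, snRNA or rRNA genes the excess of ncRNA genes was 2.91-fold in place of 7.68-fold. Of 261 miRNA genes 8 had a summit, against 1.30 at random (6.15-fold, adjusted permutation p = 0.0090). The call was lost in the stronger part of the peaks, at 4.89-fold (adjusted permutation p = 0.099). It held at 14.2-fold when only summits inside the gene counted (adjusted permutation p = 0.014) and at 14.7-fold without summits near those short RNA genes (adjusted permutation p = 0.0033), a setting chosen after the data were seen. piRNA genes had fewer than random placement gave, 15 of 15363 against 57.7 (0.260-fold, adjusted permutation p = 0.0036). With only summits inside the gene counted they were at 0-fold and no longer passed (adjusted permutation p = 0.486). lincRNA genes (3 of 194, against 2.50), antisense RNA genes (3 of 100, against 0.998) and nuclear rRNA genes (0 of 20, against 0.093) did not pass the test. Their adjusted permutation p was 1 for lincRNA and rRNA and 0.182 for antisense RNA, which went from 3.01-fold to 1.98-fold without replicate 1.

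**Figure D2:**
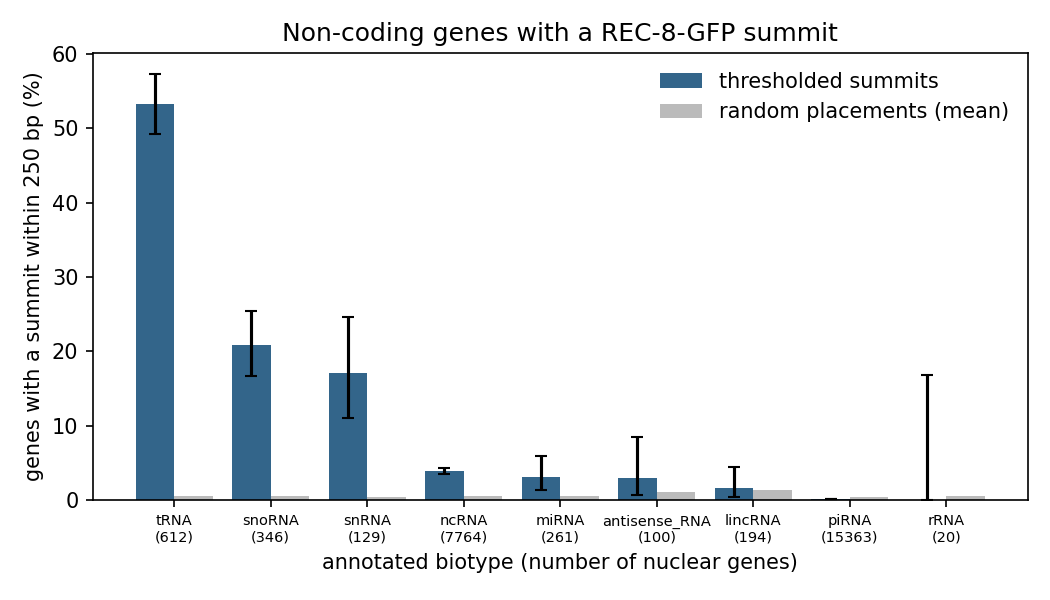
Percent of the nuclear genes of each non-coding biotype with a thresholded summit within 250 bp (blue, with exact 95% intervals) and the mean over 1000 random placements (grey). tRNA genes reach 53.3%, snoRNA genes 20.8% and snRNA genes 17.1%.

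Chromosome X held more summits than its length gives. It carried 165 of the 733 nuclear summits (22.5%, interval 19.5 to 25.7), against 17.7% of the nuclear length (exact binomial p = 0.00082, 2-sided) and 13.7% of protein-coding genes (p = 1.1e-10). X also carries 276 of the 612 tRNA genes (45.1%). Summits farther than 250 bp from a tRNA gene were rarer on X, with 17 of 437 (3.89%). Without the summits near tRNA, snoRNA, snRNA or rRNA genes, the X share was 4.09% (14 of 342, exact binomial p = 3.0e-14), below the share of its length. Chromosome III carried 17.7% of the summits on 13.7% of the length, and V 13.8% on 20.9%. These 2 shares were not tested. Of all thresholded peaks III held 17.6%, and 14.9% in the stronger part, closer to its share of the length.

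**Figure D3:**
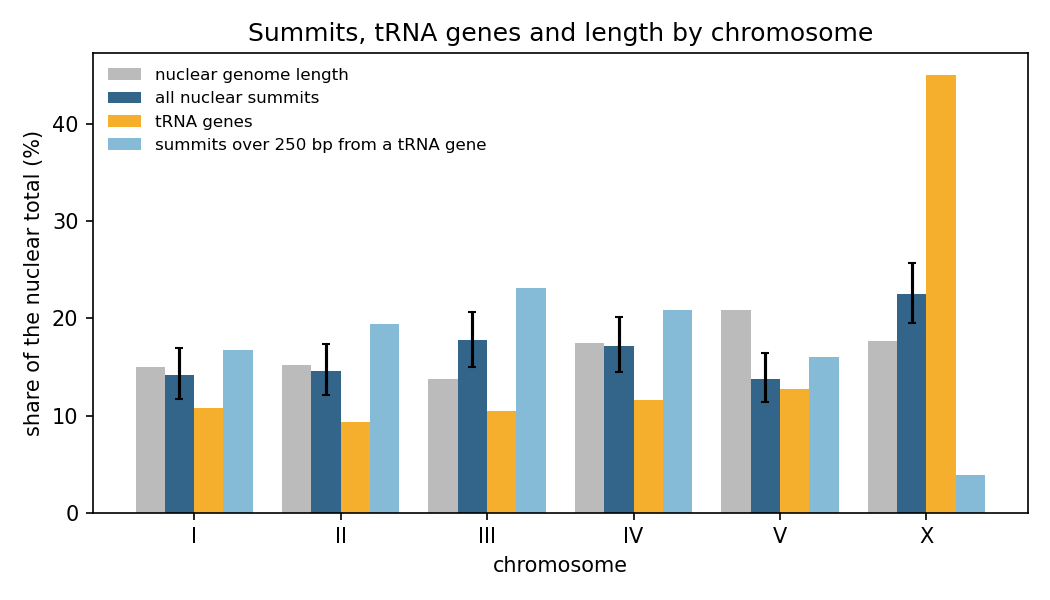
Share of each nuclear chromosome in the genome length (grey), in the 733 summits (dark blue, exact 95% intervals), in the 612 tRNA genes (orange) and in the 437 summits over 250 bp from a tRNA gene (light blue), in percent. X has 45.1% of the tRNA genes, 22.5% of the summits and 3.89% of the summits away from tRNA genes.

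On the autosomes, the outer parts of the chromosomes held fewer summits than their length gives. Of 568 autosomal summits, 300 (52.8%, interval 48.6 to 57.0) lay in the outer 30% at either end, against 60% of the length (exact binomial p = 0.00060, 2-sided). Against the 54.6% of autosomal protein-coding gene starts in these parts the difference did not pass the test (exact binomial p = 0.399).

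Summits lay near protein-coding starts more often than random placements and rarely in coding sequence. The window around a start held 361 of the 733 summits (49.2%, interval 45.6 to 52.9), against 31.2% ± 1.77 (SD over 1000 random placements, permutation p = 0.0020). Without summits near tRNA, snoRNA, snRNA or rRNA genes, the share was 69.0% (236 of 342), against 32.2% at random (permutation p = 0.0020). The excess was thus carried mostly by summits away from those short RNA genes, a setting chosen after the data were seen. Coding exons held 4.77% of the summits, against 24.2% at random (adjusted permutation p = 0.0060). 5′ UTRs held 2.86% against 1.42% (adjusted permutation p = 0.012). Genes other than protein-coding ones held 18.8% against 3.82% (adjusted permutation p = 0.0060). Introns (32.1% against 33.6%), intergenic sequence (37.0% against 33.5%) and 3′ UTRs (4.50% against 3.41%) did not pass, with adjusted permutation p of 0.396, 0.072 and 0.163. From 2000 bp upstream to the gene end, the share was 81.7% against 81.2% at random (permutation p = 0.699).

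Among the fixed gene lists, cytosolic ribosomal protein genes were marked beyond the background. Of 19973 protein-coding genes, 469 (2.35%) had a summit in the window, and 16 of the 78 ribosomal protein genes did (20.5%, 8.74-fold over the expected 1.83, adjusted Fisher's exact p = 4.5e-10). The strongest were rpl-3 (signal 372), rpl-35 (342), rpl-15 (263) and rps-23 (187). Windows were drawn around every transcript start, and the summits counted for rpl-29, rpl-31 and rpl-32 lay past the 3′ end of the gene. With a window of 250 bp on each side the list was at 3.66-fold and no longer passed (adjusted Fisher's exact p = 0.237), and with the window to the gene end it was at 4.44-fold and passed (adjusted exact p = 3.8e-05). Of 72 histone genes 6 had a summit (3.55-fold, adjusted Fisher's exact p = 0.052), the neighbours his-59 and his-60 (signal 164), his-67 and his-68 (127) and his-61 and his-62 (114.6). Each pair shares a summit, so the 6 genes rest on 3 summits, while the test counts them as 6 independent genes. The last pair lies outside the naming rule and was named after its values were seen. Histones passed without replicate 1 (5.04-fold, adjusted Fisher's exact p = 0.0014) and without replicate 2 (3.57-fold, adjusted exact p = 0.033). They also passed in the stronger part of the peaks (5.41-fold), on autosomes (3.59-fold) and without summits near short RNA genes (4.998-fold), with adjusted exact p of 0.048, 0.049 and 0.0095. They did not pass with 250 bp on each side (3.96-fold, adjusted exact p = 0.237) or to the gene end (2.06-fold, adjusted exact p = 0.212). None of the histone summits lay near short RNA genes, so leaving such summits out kept the same 6 genes and lowered the background share.

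The lists of cohesin and meiosis did not pass in the thresholded peaks. Of 14 cohesin genes 1 had a summit, smc-3 (signal 113), which encodes a core cohesin subunit (3.04-fold, adjusted Fisher's exact p = 0.531). In the lists of replicate 2 and replicate 1 alone cohesin was at 6.48-fold and 6.12-fold and did not pass (adjusted exact p = 0.092 and 0.123). Of 14 genes of the meiotic axis and synaptonemal complex 2 did, syp-4 (signal 159) and syp-6 (101), with 6.08-fold and adjusted exact p = 0.139. This list passed without replicate 2 (9.18-fold, adjusted exact p = 0.028) and did not without replicate 1 (6.48-fold, adjusted exact p = 0.092). Not all genes behind the single-replicate values of the cohesin and meiotic axis lists were named. The tagged gene rec-8 may be among them. Its best peak had rank 295 in replicate 1 and rank 445 in replicate 2. The pass may therefore rest on the tagged gene itself, which was not tested. Of 36 recombination and pairing genes 1 had a summit, him-5 (99.9), with 1.18-fold and adjusted exact p = 0.829, and 0 did without replicate 1. Of 39 germ line and oocyte genes 2 did, cpg-1 (198) and pie-1 (104.3), with 2.18-fold and adjusted exact p = 0.499, and 3.49-fold without replicate 1 (adjusted exact p = 0.116). Of 15 condensin and dosage compensation genes 2 did, mix-1 (98.0) and hcp-6 (95.7), with 5.68-fold and adjusted exact p = 0.139, and this list was at 3.03-fold without replicate 1 and 0-fold without replicate 2. In the stronger part of the peaks smc-3, syp-6, him-5, pie-1, mix-1 and hcp-6 had no summit. The summits at syp-4 and him-5 also lay near a tRNA, snoRNA, snRNA or rRNA gene. The him-5 summit (V, 14092478) lay past the 3′ end of the gene, in the window of a later transcript start. With 250 bp on each side and to the gene end, folds were 6.79 and 1.77 for cohesin, 6.79 and 3.54 for the meiotic axis, 4.88 and 1.27 for the germ line and 12.7 and 3.30 for condensin, and no list of this group passed.

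The other lists did not pass in the thresholded peaks either. Heat shock genes had summits at 3 of 23, hsp-60 (signal 158), hsp-90 (141) and hsp-110 (106), with 5.55-fold and adjusted Fisher's exact p = 0.080. They passed without summits near short RNA genes (7.82-fold, adjusted exact p = 0.032). None of the heat shock summits lay near such genes, so the same 3 genes were set against a lower background share. Translation factors had summits at 3 of 37, eif-2Bgamma (139), eif-3.C (126) and eef-2 (121), with 3.45-fold and adjusted exact p = 0.139. They passed without replicate 1 (4.91-fold, adjusted exact p = 0.043) and were at 2.32-fold without replicate 2 (adjusted exact p = 0.494). The proteasome had 1 of 33, rpn-3 (106), with 1.29-fold and adjusted exact p = 0.829, and 2.75-fold without replicate 1 (adjusted exact p = 0.308). Hypodermis and cuticle genes had 5 of 173, among them col-85 (215), col-63 (127), col-185 (126) and col-71 (114), with adjusted exact p = 0.829. Markers of body muscle (24 genes), intestine (25), neurons (32) and the major sperm proteins (31) had 0 summits, with adjusted exact p = 1 each. The expected counts were 0.564, 0.587, 0.751 and 0.728, so 0 summits cannot show that these lists are avoided. The summits at eif-2Bgamma, col-85 and col-185 also lay near a tRNA, snoRNA, snRNA or rRNA gene. hsp-110 and rpn-3 share 1 summit (III, 8447081), which counts in both lists. To the gene end heat shock was at 3.23-fold and the proteasome at 3.0-fold, and neither passed (adjusted exact p = 0.212 each).

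The tagged gene rec-8 and the kleisin genes coh-3 and coh-4 had no thresholded peak within 1000 bp. For rec-8 (WBGene00004333, IV, 13349122 to 13353193) the highest pooled signal was 80.8, rank 1008 of 10019. In the single lists its best peak had rank 295 in replicate 1 (signal 71.8) and rank 445 in replicate 2 (59.9), both within the 739 strongest. The highest pooled signal was 73.0 at coh-3 (V, 14457422 to 14460141) and 75.5 at coh-4 (V, 4169912 to 4175640). At unc-119 (III, 10902641 to 10908935), a marker often used to rescue transgenic worms, the pooled list had 0 peaks, replicate 1 had 3 (highest signal 28.9) and replicate 2 had 1 (26.7).

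In the screen of 175 gene classes, rpl (9 of 47 genes, 8.15-fold, adjusted Fisher's exact p = 0.00022) and rps (7 of 31, 9.62-fold, adjusted p = 0.00053) passed. Neither passed with 250 bp on each side, at 4.05-fold and 3.07-fold (adjusted Fisher's exact p = 1 each). In the stronger part of the peaks rps was at 9.43-fold and did not pass (adjusted exact p = 0.226), and with the window to the gene end rpl was at 3.69-fold and did not (adjusted exact p = 0.077), while rps passed at 5.59-fold (adjusted exact p = 0.034). The next classes were sec (4 of 19, adjusted exact p = 0.051), cox (3 of 15, adjusted p = 0.208) and his (6 of 72, adjusted p = 0.240). On the lower side str, a family of chemoreceptor genes, had 0 of 193 (adjusted exact p = 0.401), and clec, nhr, srx and srw followed with adjusted p of 0.659, 0.973, 1 and 1. With the window to the gene end sec (6.51-fold) and str (0-fold) passed, with adjusted exact p = 0.045 each. Without replicate 1 sec (9.56-fold, adjusted exact p = 0.030) and his (5.04-fold, adjusted exact p = 0.011) passed as well.

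Sequence at the summits was richer in G and C than its surroundings. Mean GC content was 43.1% ± 6.44 (SD, 733 summits), against 35.4% in random placements (permutation p = 0.0020). In the flanks on both sides it was 36.9% (sign-flip permutation p = 0.00020, the smallest the sign flips can give). Summits near tRNA genes made up 40.4% of the total. GC content was not computed without summits near short RNA genes, so their part in this difference is unknown. Of 2080 6-mers, 413 were more frequent and 243 less frequent at summits than in flanks. The leading ones were CGAACC (33.4% of summits against 6.003% of flanks), GTTCGA (38.7% against 8.87%), GAACCC (27.7% against 5.87%), ACCACT (26.6% against 7.23%) and AGAGCG (20.1% against 4.09%). Their adjusted exact McNemar p ranged from 8.5e-39 to 5.1e-20. The first 3 overlap in sequence and match the B box, an internal promoter element of tRNA genes. Less frequent at summits were AGATAT (5.73% against 16.4%), CTGAAA (20.6% against 35.7%), CAATTA (7.91% against 18.3%), AATTGT (16.8% against 28.9%) and TTAGAA (8.87% against 19.1%). For AGATAT the ratio of summits with the 6-mer only at the summit to those with it only in the flank, with 0.5 added to each count, was 0.294, and 0.565 without replicate 1 (adjusted exact McNemar p = 0.013). For CAATTA this ratio was 0.380, and 0.646 without replicate 2 (adjusted exact McNemar p = 0.026).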

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

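The test below was chosen after the mitochondrial peaks had been seen. Mitochondrial peaks, which entered no comparison except replicate overlap and rank correlation, made up 17 of the 739 strongest peaks of replicate 2 (2.30%, interval 1.35 to 3.66) and 0 of the 739 strongest of replicate 1. Their presence in 1 replicate, outside the nuclear genome to which the other comparisons were limited, drew attention. A candidate explanation is more mitochondrial DNA in the replicate 2 immunoprecipitate than in the control. The 18 mitochondrial peaks of replicate 2 covered 6381 of 13794 bp, or 46.3% of the mitochondrial genome, above the 30% set for a broad excess. Their rough coverage was known when that bound was set, so this is a description more than a test. Peaks of replicate 2 had a median width of 444 bp, so 18 of them cover much of so short a genome unless they overlap. The coverage therefore cannot tell a broad excess from separate peaks. The depth of either replicate is unknown, the labels point to different protocol documents for the replicates, and no biological explanation was tested.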

How the results depend on the processing

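Leaving out summits near tRNA, snoRNA, snRNA or rRNA genes, merging overlapping peaks and keeping tRNA genes without a neighbour in reach were chosen after the data were seen. Replicate overlap, rank correlation, peak count, GC content, 6-mers and the shares on X and near starts kept their direction and call under the alternatives fixed before the data were examined, with these exceptions. Against gene starts the arm share of 52.8% no longer passed the test (54.6% expected, exact binomial p = 0.399). From 2000 bp upstream to the gene end the promoter share was 81.7% (81.2% at random), a window that covers most of the genome. Without summits near those short RNA genes the X share turned from above to below its length, at 4.09%, and 3 of 5 remaining biotypes passed, fewer because the other classes were removed.

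The number of gene lists past the threshold was 1 as reported, 2 in the stronger part of the peaks, 3 in each replicate alone (3 to 3), 3 without summits near short RNA genes, 0 with 250 bp on each side and 2 on autosomes. Gene classes went from 2 to 1 in the stronger part, 2 to 4 without a replicate (4 without replicate 1) and 0 with 250 bp on each side. Apart from the lower background share without summits near short RNA genes, the cause was not tested. Ratios to expectation that turned did so on few genes, none past the threshold on either side. In the stronger part, cohesin, recombination, proteasome and condensin lists fell to 0. Over the lists of either replicate alone, recombination ranged from 0 to 1.19, condensin from 0 to 3.03 and hypodermis from 0.991 to 1.31. With 250 bp on each side recombination, proteasome and hypodermis were at 0, and to the gene end body muscle was at 1.03 and neurons at 2.32. Without summits near short RNA genes recombination was at 0, hypodermis at 0.693 and lincRNA at 0.822.

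Of 27 genes named by list, 17 had a summit in the stronger part of the peaks, 23 without replicate 1, 24 without replicate 2 and 22 without summits near short RNA genes. The strongest pooled peaks were the thresholded peaks themselves, and the interval middle differed from the summit in 23 of 733 peaks, so these alternatives tested little. The count of 6-mers past the threshold, 656 as reported, ranged from 590 to 673 over 20 draws of the flank side. No paired analysis was possible because there is 1 group, and without either replicate no thresholded list or overlap can be had. Unknown depth limits any reading of weak or missing peaks.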

Other observations

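The tests on tRNA isotypes, single-copy against shared sequences, X genes, weaker peaks and GTTCGA were chosen after the peaks had been seen. The prediction for single-copy genes against random placement was written before that test was run. Of 34 threonine tRNA genes 27 (79.4%) were marked, against 52.01% of other tRNA genes (adjusted Fisher's exact p = 0.044 over 20 isotypes and the 607 genes with an isotype in RefSeq). The test counts genes as independent, although neighbours can share a summit. Among genes with no other tRNA gene in reach of the same summit, the shares were 76.7% (23 of 30) and 55.4% (226 of 408), and the call was lost on fewer genes (adjusted Fisher's exact p = 0.170). The other 19 isotypes did not pass among all genes, and ranged from 33.3% for glutamine to 76.9% for cysteine. tRNA genes on X were marked in 167 of 276 cases (60.5%) and those on autosomes in 159 of 336 (47.3%, Fisher's exact p = 0.0015). Among genes with no neighbour in reach these shares were 69.05% and 48.5% (Fisher's exact p = 3.1e-05).

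Summits at tRNA genes might reflect GC content or reads shared between identical copies. Positions matched to the summits in chromosome and GC content lay within 250 bp of a tRNA gene in 0.566% of cases and at most 1.501%, against 40.4% of summits, which argues against GC content as the whole cause. Of 143 tRNA genes with a sequence found once, 50 (34.97%) had a summit, against at most 3.50% at random. So did 35.3% of those with no shared-sequence gene in reach, which argues against reads shared between exact copies as the whole cause. Copies were defined by an exact match over the whole gene, so reads shared between near-identical genes were not tested. Genes with shared sequence were marked more often (58.8%, Fisher's exact p = 5.7e-07), and among genes with no neighbour in reach in 64.2% against 33.04% of cases (Fisher's exact p = 1.2e-08), so shared reads may add to the pattern. Whether the signal belongs to REC-8 or to any GFP-tagged protein or open chromatin stays open, since no other tag or untagged sample is analysed here, and no biological explanation was tested.

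The higher share of summits on X may come from its tRNA genes. Away from tRNA genes, X held 3.89% of 437 summits (interval 2.28 to 6.16), below its 17.7% of the length, which is consistent with tRNA genes as the source. More X DNA in the immunoprecipitate than in the control was predicted to raise the weaker peaks on X above its share of the length. X held 12.3% of the 9280 weaker pooled peaks (interval 11.7 to 13.04), below that share. Strong summits away from tRNA genes were also rarer on X than its length gives, so the length is a poor yardstick for such peaks. The test therefore cannot decide whether more X DNA adds to the higher share. Why X has few summits elsewhere stays open.

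A hypothesis was that an internal promoter of RNA polymerase III genes also marks summits without an annotated tRNA gene. GTTCGA occurred at 17.8% of 437 such summits and in 7.78% of their flanks (exact McNemar p = 2.3e-05), an excess in the predicted direction at a minority of them. It was a leading 6-mer over all 733 summits, which include these, so the test is not independent of that choice. Over all summits GC content was 43.1%, against 36.9% in flanks, and 413 of 2080 6-mers were more frequent at summits. The test therefore cannot tell an internal promoter from base composition. The excess may also reflect unannotated tRNA-like sequence, which was not tested.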
